A study of Mus musculus with 8 samples.

How the data were processed

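RNA from 8 mouse spleens, 4 from miR-155 knockout and 4 from wild-type animals, was labelled with Cy3 and hybridised to 1-colour NimbleGen expression arrays, per the labels. Each genotype had 2 animals labelled female and 2 labelled male. The knockout animals carry the names Mim1-5, Mim1-6, Mim2-2 and Mim2-3, and among them the labelled sex coincides with the name prefix, Mim1 for females and Mim2 for males. The wild-type animals are numbered 1 to 4. The series describes the samples as separate spleens, so each array was taken as 1 animal.

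The authors deposited 1 table per array with an intensity for each feature on a linear scale, which the submitters' processing notes tie to RMA, with a version not given in the sources used here. RMA corrects background, normalizes between arrays and summarises the probes of a feature. Per the file headers, 44155 of the 44170 features rest on 3 probes, and their positions are those of mouse build MM9. The tables also hold a standard error score per feature, deposited by the authors, whose making is not given in the sources used here and which entered no test. A further entry summarising 5000 random probes was kept out of all tests and used as the background level. The authors also deposited a table of the series with 21856 of these features, whose values equal those of the array tables within a relative tolerance of 1e-06. It leaves out 22314 features, mostly dim ones, and the rule for leaving them out is not given in the sources used here.

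Values were transformed to log2 with no second normalization. The feature names are those of the array design. Of 24203 Entrez gene numbers in the tables, 21583 matched the NCBI reference table of assembly GRCm38.p6, which was used for current symbols alone, and the file's name was kept otherwise. In all 41889 features carried a gene name, for 24174 genes, and 2281 stayed unnamed. Where a gene had several features, gene lists used the feature with the highest mean log2 intensity over the 8 arrays, and the genes named by rank used the feature with the smallest p.

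Differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all 44170 features and a threshold of 0.05. The knockout minus wild type difference was fitted with sex as an additive term, and male minus female came from the same fit. A fit with the genotype by sex interaction gave the difference between the sexes and the genotype difference within each. Gene lists were tested with camera of limma at a preset correlation of 0.01, adjusted over 33 lists, with an estimated correlation and fry beside it, and an exact two-sided permutation test over the 70 arrangements of the arrays was run on each list's mean. The smallest p that test can give is 0.0286.

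The 33 lists, the limma and set tests and the rule for named genes were fixed before the data were examined, and the exact test of list means was added after. The rule names the miR-155 host transcript first, then the 10 named genes with the smallest p where no feature passes, up to 4 members of each list past the threshold and of the literature targets and chromosome 16 neighbours, up to 2 members of other lists, and the 5 genes with the smallest p per direction for sex and for the interaction. Some genes that this rule takes are not reported here. Lists of mammary epithelium, milk protein genes, adipocytes, liver, nervous system, intestine, kidney and lung were written after bright mammary genes had been seen on these arrays.

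Simulated arrays drew noise for each feature on its own, with the spread left by the fit with the genotype by sex interaction. There the additive knockout against wild type fit over 44170 features recovered 4.48% of 67 features changed by 1 on the log2 scale. It recovered 64.2% of 67 changed by 2 and 98.5% of 66 changed by 4, with 3 false calls. It made 0 calls with no change. That spread holds no part of the difference between the Mim1 and Mim2 arrays, which the additive fit leaves in part in its residual. So these shares are not a measure of recovery on the real arrays. Alternatives covered the source of values, normalization, filters on dim features, the variance model, array weights, the floor, the covariates, the features per gene, the set test and leaving out each array. A slide or scan block was not run, because no slide or scan is named in the tables used here, and the search for miR-155 seed matches was not run, because no 3' UTR sequence was used here. The number of arrays limits the precision.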

Results

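Spleen RNA of 4 miR-155 knockout mice and 4 wild-type mice was profiled on expression arrays to ask which transcripts differ when this microRNA, a regulator of lymphocyte and myeloid responses, is missing. Median intensities lay between 112.1 and 119.1 on the linear scale on all 8 arrays. The random probes read 30.7 to 37.7, and 81.1% to 85.0% of features lay above them. Arrays other than those of Mim2-2 and Mim2-3 correlated with each other at r = 0.911 to 0.943 over all features. The arrays of these 2 knockout males correlated with the other 6 at 0.811 to 0.877 and with each other at 0.874. The first principal component, with 36.7% of the variance, set them at scores of 158.7 and 141.0, against -77.6 to -20.0 for the other 6.

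**Figure D1:**
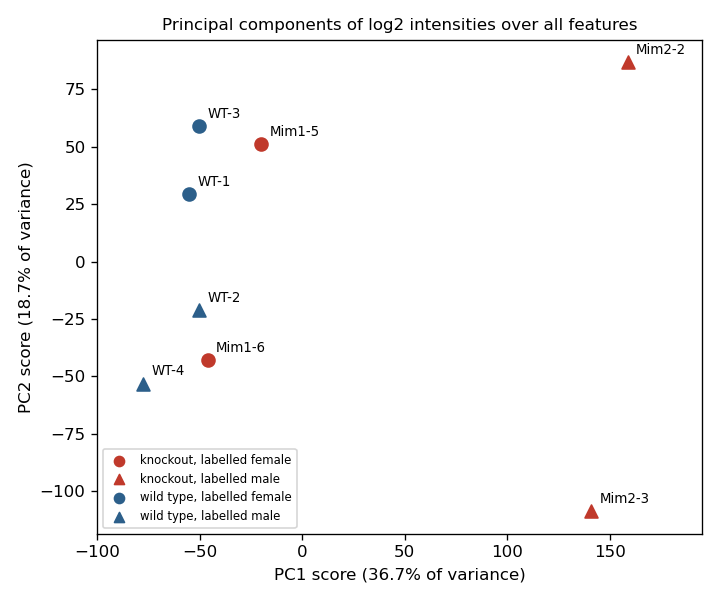
Scores of the 8 arrays on the first 2 principal components of log2 intensity, with 36.7% and 18.7% of the variance, coloured by genotype and with circles for animals labelled female and triangles for those labelled male. The knockout males Mim2-2 and Mim2-3 lie at 158.7 and 141.0 on the first component, apart from the other 6 arrays.

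The transcript BIC, from which miR-155 is processed, has 1 feature on chromosome 16 from 84713276 to 84715489 in build MM9. Its log2 intensity was 7.51 in Mim1-5, 5.37 in Mim1-6, 5.28 in Mim2-2 and 5.46 in Mim2-3, and in wild-type animals 1 to 4 it was 5.27, 4.84, 4.85 and 5.63. The difference of 0.76 did not pass (limma, adjusted p = 0.521). The random probes stood at log2 4.94 to 5.24, so 7 of these values lie near background. The position of the probes relative to the deleted part is not known, so this feature checks nothing about the knockout. The labelled sexes were also set against sex-linked genes. The X inactivation transcript Xist had log2 intensities of 8.35 to 11.1 on all 8 arrays, with means of 10.1 in labelled females and 9.95 in labelled males. The Y-linked helicase gene Ddx3y had means of 7.82 in labelled females and 7.75 in labelled males (exact permutation p = 0.914). The same Ddx3y feature read 8.66 on the knockout and 6.91 on the wild-type arrays (exact permutation p = 0.0286). The other Ddx3y features were higher in the knockout by 1.82, 1.71 and 1.19 (exact permutation p = 0.0286, 0.0286 and 0.0571). The sex-linked gene Eif2s3y was higher by 1.23 (exact permutation p = 0.0286). The brightest features of Kdm5d and Uty, also sex-linked, differed by 0.80 and 0.47 (exact permutation p = 0.2 and 0.343). These genes do not separate the labelled sexes, and "male" and "female" stand below for the arrays labelled so.

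Transcripts of the mammary gland were bright over the 8 arrays, beside those of spleen cells, but not equally on each array. Over the 8 arrays, the median gene of a 30-gene list of mammary epithelium stood at the 85.8th percentile of 24174 genes, against the 78.8th for B cell genes and 38.6 for the highest of 5 control tissues. On single arrays this median ran from the 57.4th to the 94.3rd percentile. The highest value of a control tissue on any array was 48.8, for nervous system. The median of milk protein genes fell to the 45.4th percentile on its lowest array, within the range of that control. The milk protein gene Csn2 reached a log2 intensity of 14.9 to 15.4 on the wild-type arrays. It read 13.7 in Mim1-5, 12.2 in Mim1-6, 8.22 in Mim2-2 and 13.9 in Mim2-3. The mean of the list was 9.41 ± 1.33 (SD, n = 4) on knockout and 11.15 on wild-type arrays, and every knockout array lay below every wild-type array (exact permutation p = 0.0286). In Mim2-2 and Mim2-3 it stood at 7.78 and 8.89. This list was written after such genes had been seen on these arrays, so it is not independent evidence of its direction.

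No single feature passed between knockout and wild-type spleens. limma called 0 of 44170 features, with 6122 at an unadjusted p under 0.05, of which 3085 were higher and 3037 lower in the knockout, where chance gives 2208. Leaving out 1 array gave counts from 3773, without wild-type animal 4, to 7154, without Mim1-6, with 3884 without wild-type animal 2. The count was 2726 without both Mim2 arrays and 2541 with the mean of the mammary list as a further term, both chosen after seeing the data. Without both Mim2 arrays the fit with the sex term gives the difference between 2 knockout and 2 wild-type females. The mammary mean itself separates the genotypes, so its term also takes out genotype difference. Among the 10 named genes with the smallest p, pancreatic amylase and B cell genes were higher on the knockout arrays. Amy2b, a pancreatic amylase on chromosome 3 from 112950724 to 112952607, had a log2 intensity of 11.47 ± 0.56 (SD, n = 4) in the knockout and 7.45 ± 0.70 in the wild type, a 16.2-fold difference with an adjusted p of 0.224 in limma. A second pancreatic amylase feature, Amy2a5, differed by 2.40 on the log2 scale, and amylase genes are near-identical copies whose probes may not tell them apart. Cr2, the complement receptor of B cells and follicular dendritic cells on chromosome 1 from 196963004 to 197002909, read 10.03 ± 0.50 (SD, n = 4) against 7.37 ± 0.60. The kinase gene Stk17b differed by 1.98 and the predicted gene Gm4724 read 7.26 in the knockout and 5.05 in the wild type, where it lay above the random probes on 2 of 4 arrays, so the size of its difference is not known. Lower on the knockout arrays were the casein gene Csn1s1, by -3.75, the phospholipid scramblase gene Plscr2, by -2.45, Timd2, by -2.25, and the chaperone gene Clu, by -1.97. Adjusted p was 0.262 in limma for each of these 8 genes from Amy2a5 to Clu. A variance model with trend and robust estimates called 16 features, 7 higher and 9 lower. In 3240 features, 7.34% of all, the 2 genotypes did not overlap, where chance gives 2.86%.

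Genes of B cells rose as a group in the knockout. Of 21 measured members, 17 rose when adjusted over the list alone, 0 passed adjusted over all features and 4 passed neither, with a median difference of 1.24 on the log2 scale (camera adjusted p = 4.12e-15, and adjusted p = 0.300 with an estimated correlation). The list mean was 10.40 ± 0.42 (SD, n = 4) in the knockout and 9.14 ± 0.19 in the wild type, higher on 4 of 4 knockout arrays. The kinase gene Blk rose by 1.96 ± 0.29 (SE), the coactivator gene Pou2af1 by 1.48 ± 0.27, and Fcrla by 1.75 ± 0.33, adjusted over the list alone. Antigen presentation genes rose too, 8 of 20 measured higher and 1 lower adjusted over the list alone, 0 over all features, with a median of 0.59 (camera adjusted p = 3.84e-05, and adjusted p = 0.292 with an estimated correlation). Among them the class II genes H2-DMa, H2-Ob, H2-Aa and H2-DMb1 rose by 1.39, 1.30, 1.20 and 1.06. T cell genes rose with a median of 0.57, 7 of 22 measured passing over the list alone (camera adjusted p = 2.76e-05, and adjusted p = 0.353 with an estimated correlation). The T cell median was 0.25 in females and 1.11 in males. The call was lost without both Mim2 arrays, where the difference is that same female one (camera adjusted p = 0.105). The members that passed included Cd2, higher by 1.42, Trat1 by 1.44, the interleukin 7 receptor gene Il7r by 1.17 and the kinase gene Zap70 by 0.93. The mammary list was lower on the same knockout arrays, by 1.74 in the mean.

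Other cell types of the spleen, and NF-kB and inflammatory genes, moved up as lists in which fewer members passed. None of the 4 calls that follow held without both Mim2 arrays. Genes of cytotoxic T and NK cells had a median of 0.68, with 0 of 18 members passing over the list alone (camera adjusted p = 0.00022, and adjusted p = 0.353 with an estimated correlation). Xcl1, Cd8a, Il2rb and Nkg7 differed by 1.55, 1.03, 0.92 and 0.68. Red pulp and marginal zone macrophage genes had a median of 0.69 and 0 of 16 members passing (camera adjusted p = 0.00314, and adjusted p = 0.447 with an estimated correlation), with Vcam1, Marco, Mertk and Axl differing by 1.27, 0.92, 1.24 and 0.77. Stromal and endothelial genes had a median of 0.52, and 4 of 21 members rose over the list alone (camera adjusted p = 0.000877, and adjusted p = 0.353 with an estimated correlation), namely the chemokine genes Cxcl12 and Cxcl13, Madcam1 and Tek, by 1.38, 1.52, 1.09 and 1.85, the value of Tek being inexact because it lay above the random probes on 3 of 4 wild-type arrays. NF-kB and inflammatory genes had a median of 0.57 and 0 of 25 passing (camera adjusted p = 0.0391, and adjusted p = 0.447 with an estimated correlation), among them Bcl2a1a, Il1b, Nfkb1 and Ccl5 with 1.29, 1.33, 0.81 and 0.76. The NF-kB call held in 4 of 8 settings that left out 1 array. It was lost without Mim2-2, Mim2-3 or wild-type animal 2 or 3 (camera adjusted p = 0.139, 0.0593, 0.110 and 0.0620). In females the medians of the cytotoxic, red pulp, stromal and NF-kB lists were 0.36, 0.39, 0.30 and 0.23, against 0.94, 0.69, 0.71 and 0.86 in males. Without both Mim2 arrays, where the difference is that within females, their camera adjusted p was 0.0777, 0.176, 0.0777 and 0.630. In each of these lists 0 members passed adjusted over all features.

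Genes of the pancreas, an organ next to the spleen, rose in the knockout, 11 of 23 measured over the list alone and 0 over all features, with a median of 1.19 (camera adjusted p = 2.05e-07, and adjusted p = 0.292 with an estimated correlation). The list holds exocrine genes and also hormone genes such as Ins1 and Gcg. Cela2a rose by 1.43 ± 0.38 (SE). The colipase gene Clps and Cpa1 rose as well, from wild-type means of 5.07 and 4.96 to 6.85 and 6.68. They lay above the random probes on 2 and 1 of 4 wild-type arrays, so the size of these differences is not known. The list mean was 6.68 ± 0.28 (SD, n = 4) in the knockout and 5.67 in the wild type, where the random probes stood at 5.02. Of the 23 members, 14 lay at or under the random probes on at least 1 wild-type array, so the median is not exact. With each value under the random probes set to their level, a setting chosen after seeing the data, it was 1.002 (camera adjusted p = 2.02e-06). Genes of adipose tissue and muscle had a median of 0.62 with 0 of 14 members passing (camera adjusted p = 0.0114, and adjusted p = 0.452 with an estimated correlation). Their median was -0.19 without the Mim2 arrays, which ends the call. The call was also lost without Mim2-2, Mim2-3 or wild-type animal 2 or 4, with medians of 0.43, 0.35, 0.46 and 0.30 (camera adjusted p = 0.0853, 0.0593, 0.0517 and 0.0708). The members Myh4, Plin1, Adipoq and Cidec differed by 1.11, 0.85, 2.32 and 2.62.

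Erythroid, germinal centre and proliferation genes fell as lists. The germinal centre list had a median of -0.55, and 3 of 11 members fell over the list alone (camera adjusted p = 0.0162, and adjusted p = 0.300 with an estimated correlation). These were Plxnb2 and S1pr2, with -1.59 and -0.997, and Rgs13, which lay above the random probes on 0 of 4 knockout arrays (mean 4.56, against 6.05 in the wild type) and was at least 1.98-fold lower, set against the random probes. The list's median was -0.87 without Mim1-6, and its call was lost without Mim1-5 (median -0.48, camera adjusted p = 0.0507). In this list Bcl6, the master regulator of germinal centre B cells, differed by 0.67 the other way and did not pass. Erythroid genes had a median of -0.34 with 0 of 23 passing (camera adjusted p = 0.00113, and adjusted p = 0.447 with an estimated correlation), and the list mean was 8.86 and 8.69 in the knockout females against 9.73 and 9.81 in the knockout males and 9.54 to 9.81 in the wild type. The median was -0.56 without Mim2-2, -0.22 without wild-type animal 3 and -0.61 without wild-type animal 4, and -0.90 without both Mim2 arrays. Nfe2, Epor, Car2 and Tal1 differed by -1.40, -1.33, -1.06 and -0.96. Cell cycle genes had a median of -0.56 with 0 of 33 passing (camera adjusted p = 2.74e-05, and adjusted p = 0.447 with an estimated correlation), and Kif20a, Ccna2 and Tpx2 differed by -1.53, -0.66 and -1.496. Ccnb2 read 5.53 in the knockout, where it lay above the random probes on 2 of 4 arrays, and 6.62 in the wild type.

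TGF-beta and SMAD genes had a median of -0.37, and 4 of 19 fell over the list alone (camera adjusted p = 0.000479, and adjusted p = 0.353 with an estimated correlation), namely Tgfb3, Bmpr1a, Tgfb2 and Smad3 with -2.47, -1.40, -1.81 and -1.09, the value of Bmpr1a being inexact because it lay above the random probes on 3 of 4 knockout arrays. Glycolysis and hypoxia genes had a median of -0.63 with 0 of 21 passing (camera adjusted p = 3.84e-05, and adjusted p = 0.447 with an estimated correlation), with Egln3, Slc2a1, Pfkl and Pkm at -2.05, -1.30, -1.02 and -0.83. Unfolded protein response genes had a median of -0.32 with 0 of 17 passing (camera adjusted p = 0.00511, and adjusted p = 0.447 with an estimated correlation), and Trib3, Xbp1, Pdia3 and Calr differed by -2.34, -1.24, -0.88 and -0.61. The median of this list was -0.57 without Mim1-6, -0.51 without wild-type animal 1 and -0.56 without wild-type animal 3. In all 6 lists that fell, 0 members passed adjusted over all features. The mammary genes other than those of milk proteins had list means of 7.91 and 8.77 in Mim2-2 and Mim2-3, 10.98 and 11.06 in Mim1-5 and Mim1-6, and 11.14 to 11.42 in the wild type. Milk protein genes were lower in both pairs, with a median of -2.28 in females and -1.81 in males. Without these 2 arrays the cell cycle, TGF-beta, glycolysis and unfolded protein lists, and those of T cells, cytotoxic cells, red pulp macrophages, stroma and NF-kB, did not pass. The medians of the first 4 were then -0.07, -0.17, -0.12 and -0.02 (camera adjusted p = 0.430, 0.333, 0.430 and 0.630). In all, 8 lists passed in place of 15, and 5 of the 15 were among them. These 8 calls rest on the difference within females, with 2 arrays per genotype, and the 15 on 4 arrays per genotype.

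Published targets of miR-155 did not pass as a list. The median of 46 measured targets was 0.14 on the log2 scale, 26 higher and 20 lower, and 0 passed over the list alone or over all features. For the list the camera adjusted p was 0.535, or 0.559 with an estimated correlation, and the fry adjusted p was 0.112. At an unadjusted p under 0.05 in limma, 7 targets were higher and 2 lower, where 3545 of all 24174 genes had such a p. The phosphatase gene Inpp5d, which encodes SHIP1, differed by 0.97 ± 0.28 (SE), Sla by 1.30 ± 0.38, Bach1 by -0.95 ± 0.28 and Wee1 by -1.34 ± 0.52. Genes next to the miR-155 gene on chromosome 16 had a median of -0.10 over 26 genes, with 0 passing (camera adjusted p = 0.0809, and adjusted p = 0.353 with an estimated correlation). Without wild-type animal 4 this list passed (median -0.04, camera adjusted p = 0.0494). In it Bach1, App and Ltn1 differed by -0.95, -1.10 and -0.63. Chodl read 4.73 in the knockout and 6.37 in the wild type, above the random probes on 1 of 4 and 3 of 4 arrays, so the size of its difference is not known.

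**Figure D2:**
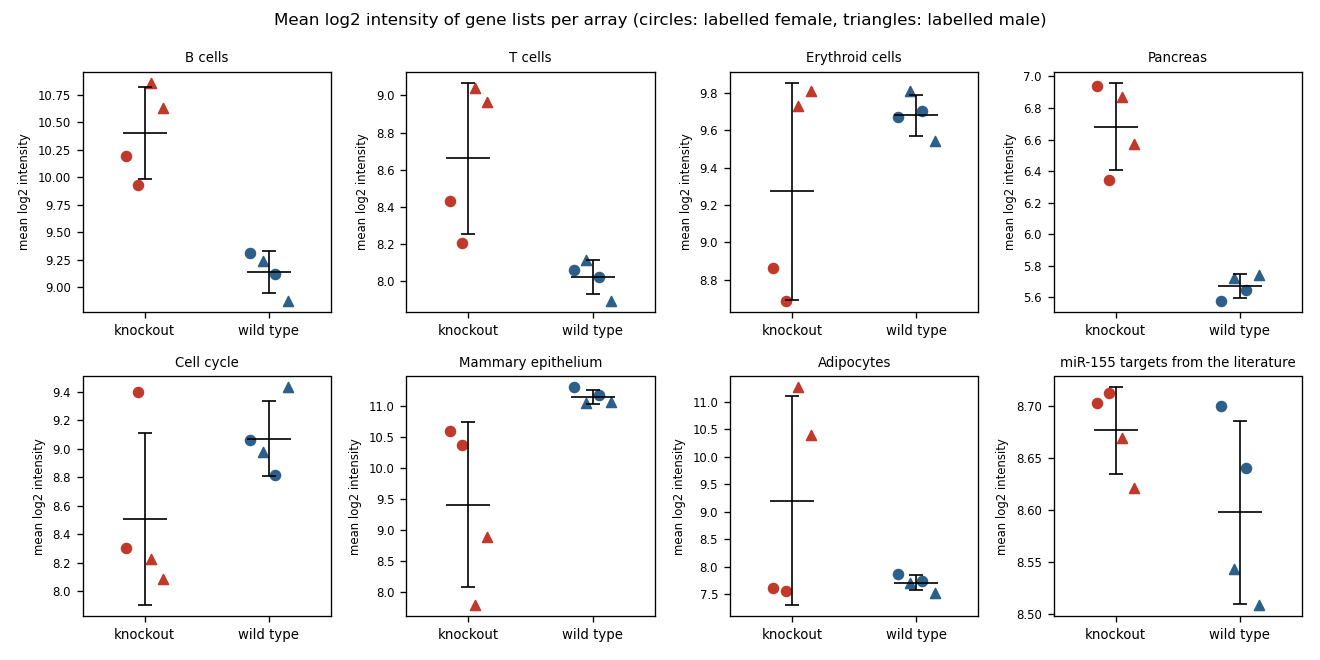
Mean log2 intensity of 8 gene lists on each array, with a bar for the mean and error bars of 1 SD over 4 arrays per genotype, circles for animals labelled female and triangles for those labelled male. The B cell and pancreas lists lie higher on all 4 knockout arrays than on the wild-type arrays, and the mammary list lies at 7.78 and 8.89 in the knockout males.

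The other 16 lists did not pass in camera, with adjusted p from 0.0535 to 0.894, and members named by rank are given as values. Neutrophil genes had a median of -0.30 and 4 of 21 members lower over the list alone, among them Camp with -1.67 and Ltf, the gene of lactoferrin, which is also a milk protein, with -2.33. This list passed without Mim2-2, Mim2-3 or wild-type animal 2 or 4 (camera adjusted p = 0.0201, 0.00619, 0.0270 and 0.00538), and without both Mim2 arrays (median -0.63, camera adjusted p = 2.24e-06). Dendritic cell genes had a median of 0.29 with 4 of 16 higher over the list alone, Cd83 by 1.19 and Siglech by 1.31, and passed without Mim1-6 or wild-type animal 4 (camera adjusted p = 0.0491 and 0.0488). Plasma cell and immunoglobulin genes had a median of -0.26, with Derl3 at -2.32 and Fkbp11 at -1.40. Regulatory T cell genes had 0.15, with Il2ra at 1.28 and Tnfrsf18 at 0.87. T helper genes had -0.02, with Gata3 at -1.23 (-0.15 in females and -2.31 in males). Monocyte and macrophage genes had 0.30, with Ctsb at -0.91 and Cd14 at -1.32. Megakaryocyte genes had 0.39, with Plek at 1.06 and Ppbp at 1.39. Mast cell genes had 0.34, with Gata2 at 1.02 and Kit at -0.87 (0.16 in females and -1.90 in males). Interferon-stimulated genes had -0.06, with Cxcl10 at 1.05 and Gbp4 at 0.92, and passed without wild-type animal 4 (median 0.37, camera adjusted p = 0.00489) and without both Mim2 arrays (median 0.53, camera adjusted p = 0.0168). Immediate early genes had 0.06, with Egr2 at 1.41 and Junb at -1.66, and heat shock genes 0.19, with Hspa1b at -1.85 and Hspe1 at 0.82. Cytokine signalling suppressors had -0.15, with Socs2 at -2.10 and Stat3 at -0.92. Ribosomal protein genes had 0.14, with Rpl5 at 0.81 and Rpl27 at 0.55, and oxidative phosphorylation genes 0.01, with Uqcrfs1 at 0.88 and Atp5d at -0.77. Heme synthesis genes had -0.15, with Ppox at -1.07 and Cpox at -0.57, and passed without wild-type animal 4 (camera adjusted p = 0.0494) and without both Mim2 arrays (median -0.47, camera adjusted p = 0.0229). Cholesterol synthesis genes had -0.02, with Hmgcs1 at 0.64.

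Between the labelled sexes no feature passed. limma called 0 of 44170, with 3995 at an unadjusted p under 0.05 and a smallest adjusted p of 0.551. The count of 3995 was 2000 without Mim1-5, 2472 without Mim2-3 and 4531 without wild-type animal 4. The genes with the smallest p that were higher in males were Ablim3, at a log2 intensity of 9.38 in males and 7.27 in females, Hsd11b1, at 8.11 and 6.14, Gm8362, H2al1i and Gm2030. Those higher in females were Vwc2, at 8.42 in females and 6.33 in males, Slc26a1, Hs2st1, Papolg and BC021767. Of these, H2al1i, Gm2030, Slc26a1, Hs2st1 and Papolg lay at or under the random probes on at least 1 array. In the knockout, sex cannot be told apart from the name prefix.

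The genotype difference was then compared between the sexes. The interaction called 0 of 44170 features in limma, with 5872 at an unadjusted p under 0.05 and a smallest adjusted p of 0.106, and other settings called up to 578. The genes with the smallest p and a positive value included fat cell genes. Cidec, a lipid droplet gene of adipocytes on chromosome 6 from 113374629 to 113385754, was at 11.63 in knockout males, 5.57 in wild-type males, 5.18 in knockout females and 6.01 in wild-type females. The adipocyte genes Aoc3 and Car3 had interaction values of 5.84 and 5.55, with C4a at 3.99. Gm13582, above the random probes on 0 of 2 arrays of wild-type males and 1 of 2 of knockout females, had 3.88, whose size is therefore not exact. Epithelial and other genes went the other way, with St8sia6 at -6.07, Dab2ip at -5.07, the transcription factor gene Sox9 at -5.01, Sec14l1 at -4.14 and Ank3 at -4.46, a value that is not exact because Ank3 lay above the random probes on 1 of 2 arrays of knockout males. Adjusted p was 0.106 for Cidec, Aoc3 and St8sia6 and 0.162 for the other 7.

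Within males, where 2 knockout arrays met 2 wild-type arrays, 1875 features passed, 397 higher and 1478 lower in the knockout. Cidec rose by 6.06 ± 0.44 (SE), Aoc3 by 4.58 ± 0.39 and Car3 by 4.65 ± 0.43, while St8sia6 fell by 5.30, Sox9 fell by 4.95 and Dab2ip fell by 4.83 (limma, adjusted p = 0.0216 for all 6). Within females 0 features passed in limma, with 2274 at an unadjusted p under 0.05. The male count was 263 without Mim1-5 or without Mim1-6, 0 without Mim2-2, and 0 without any 1 of the 4 wild-type animals. Without Mim2-3 it was 1476. The female arrays enter this count through the shared estimate of the spread. The knockout males are the Mim2 arrays that stand apart, and the sex, the name prefix and these 2 arrays cannot be separated in the knockout.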

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

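The tests of the 3 patterns weighed here and the counts over other splits of the arrays were chosen after the results had been seen.

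In 163 genes and lists, 326 groups of 4 arrays were searched for an array far from the other 3. There were 12, where chance would give about 16.3. BIC was at 7.51 in Mim1-5, Csn1s1 at 9.30 in Mim2-3 and Xcl1 at 6.16 in Mim1-6. Among wild-type arrays, Amy2b was at 6.40 in animal 4, Nkg7 at 10.8 in animal 2, Epor at 9.73 in animal 4, Rgs13 at 7.25 in animal 1, Tnfrsf18 at 10.4 in animal 3, Rpl5 at 12.2 in animal 4 and Bmpr1a at 6.67 in animal 4. The list mean of T helper genes was 6.86 and that of cell cycle genes 9.40 in Mim1-6.

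Genotype differences that ran in opposite directions in the 2 sexes on every array were found for 7 genes and 1 list. For the genes the interaction missed the threshold. Male minus female differences were 6.89 for Cidec, 5.84 for Aoc3, 5.55 for Car3, 3.88 for Gm13582 (not exact, as it lay above the random probes on 0 of 2 arrays of wild-type males), 3.99 for C4a, -6.07 for St8sia6 and -4.14 for Sec14l1. The mean of the adipose tissue and muscle list differed by 2.39. By camera on the interaction, 13 lists passed and none did with an estimated correlation (adjusted p from 0.141 to 0.572). Their median interaction values were 1.45 for adipose tissue and muscle, 1.16 for neutrophils, 1.11 for erythroid cells, 0.95 for monocytes and macrophages, 0.80 for B cells, 0.68 for T cells and 0.53 for regulatory T cells. They were -1.08 for cell cycle, -0.88 for interferon-stimulated genes, -0.86 for the unfolded protein response, -0.85 for glycolysis and hypoxia, -0.74 for TGF-beta signalling and -0.55 for cytokine signalling suppressors.

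Mammary epithelial genes were bright over the 8 arrays labelled spleen, with a list median between the 57.4th and the 94.3rd percentile on single arrays. The list had been prompted by some of its own members, so the test used the 11 members that had not been looked at before it was written. Over the 8 arrays their median stood at the 81.3rd percentile, 42.7 points above the highest of 5 control tissues. This argues against unspecific background on tissue-specific probes, and single arrays were not tested. The value is consistent with RNA of mammary epithelium in the samples, as a hypothesis, and whether it entered by dissection, by mixing of RNA or by a wrong tissue label was not tested. Csn2 read 15.35 and 14.9 on the wild-type arrays labelled male and 15.35 and 15.41 on those labelled female. Sex-linked genes did not separate the labelled sexes either, and whether the labels of sex and tissue are right was not tested. No biological explanation was tested.

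The arrays of Mim2-2 and Mim2-3 stood apart from the other 6. Their log2 intensities had a narrower range, with interquartile ranges of 3.03 and 2.98 against 3.29 to 3.39 on the other 6. Normalizing all arrays to one distribution left 1915 features past the threshold in males, which argues against a compressed signal range as the whole cause. The 8 mammary genes not looked at before had a median of -2.08 in males, which is consistent with less epithelial RNA in these 2 samples, although milk protein genes were lower in both pairs of knockout arrays (median -2.28 in females, -1.81 in males). More fat in them stays open, because only 3 adipocyte genes had not been looked at, with a median of 2.08. Genotype, labelled sex and litter or line behind the name prefix stay open and untested.

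B cell genes were higher on the knockout arrays. Less epithelial RNA alone would raise genes that only spleen cells express alike, as long as they read well above background. The T cell, cytotoxic, red pulp macrophage and stromal lists rose too, with list means higher by 0.64, 0.64, 0.56 and 0.56. The B cell list rose by 1.67 more than the erythroid list. The erythroid mean was 8.86 and 8.69 in knockout females, 9.73 and 9.81 in knockout males and 9.54 to 9.81 in wild type. The B cell list also rose by 0.629 to 1.59 more than each of 10 other lists of spleen cells. The exact permutation p was 0.0286 for each of the 11, with an adjusted p of 0.0286, the smallest the test can give. All 11 comparisons share the B cell list, which by itself separates the genotypes, so they are not separate tests. The T cell, dendritic cell and megakaryocyte lists also lay higher on all 4 knockout arrays than on all wild-type arrays. In some lists members lay under the random probes on at least 1 array, 7 of 21 for neutrophils and 5 of 12 for mast cells. In the T cell and B cell lists 0 did. The gap of 0.629 between these lists argues against less epithelial RNA as the whole cause but not as a part. The knockout arrays other than Mim2 lay 0.925 above the wild type and above each of its arrays, so the Mim2 arrays alone do not carry the difference. A different share of tissue taken with each spleen and an effect of the genotype may both account for it and were not separated.

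Of the 35 splits of the 8 arrays, 34 could be fitted beside the other factor. The real split called 0 features between genotypes, as did all 34 (highest other 0), and likewise 34 of 34 between sexes, so these counts exclude nothing. At an unadjusted p under 0.05 the genotype count of 6122 was reached by 1 split, the real one (highest other 5642), a share under 0.05. That highest other split keeps both Mim2 arrays on one side, and the splits that part them reached at most 4236. So no other split gave as large a count, but the tally does not tell the genotype from these 2 arrays. The count was 7154 without Mim1-6, 3884 without wild-type animal 2 and 3773 without wild-type animal 4. It was 2726 without both Mim2 arrays and 2541 with the mammary term, where chance gives 2208. Other splits were not run in these settings. The sex count of 3995 was reached by 4 splits (highest other 4369), so chance was not excluded. It was 2000 without Mim1-5, 2472 without Mim2-3 and 4531 without wild-type animal 4. The 15 lists were reached by 1 split, the real one, and the highest other had 14. Both other splits with 14 lists keep the Mim2 arrays on one side, and the 20 splits that part them reached at most 10.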

How the results depend on the processing

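The alternatives without both Mim2 arrays, with the array set of the second principal component or the mammary list mean as a further term, the exact test of list means, the level of the random probes as a floor for lists and all those for the counts within each sex were chosen after seeing the data. The array set was read from the data and served as a covariate alone. Without both Mim2 arrays the genotype difference is that within females. The cause of a change was not tested unless stated. Knockout against wild type gave 0 features under every alternative except the variance model with trend and robust, which gave 16. Male against female gave 0 under each. The interaction gave 311 with the series table, 242 without the features below the median brightness, 578 with trend and robust, 3 with log2(value + 16) and 1 with the mean of a gene's features, and 0 under the others. Within females the count stayed 0. Within males it was 4830 with the series table, 2904 without the features in the lowest quartile of brightness, 4753 without those below the median, 4266 with trend and robust, 1041 with array weights, 2883 with log2(value + 16), and 1144 and 1070 with 1 value per gene, the brightest feature or the mean. Leaving out 1 array gave 0 to 1476. The 15 lists became 8 without both Mim2 arrays, 7 with the mammary term, 4 with fry, 0 with an estimated correlation, 16 with the floor, which added neutrophils (adjusted p = 0.0358), and 0 with the exact test, whose smallest adjusted p here was 0.105. The 7 with the mammary term were 4 higher and 3 lower. They included neutrophils and interferon-stimulated genes, which had not passed before, and adipose tissue and muscle in the other direction. So most of the 15 calls were lost with that term, among them NF-kB and the unfolded protein response. The mammary mean lay lower on every knockout array than on every wild-type array, so the term also takes out genotype difference. The lost calls therefore do not tell mammary RNA from genotype. Leaving out 1 array gave 14 to 19 lists. Of lists that did not pass, dendritic cells passed without the sex term, with the series table and after quantile normalization or median centring (adjusted p = 0.0484, 0.0099, 0.0492 and 0.0495). Without the features in the lowest quartile of brightness they passed (0.0382), as did neutrophils (0.0425) and regulatory T cells (0.0480). With the mean of a gene's features neutrophils (0.0458) and heme synthesis (0.0192) passed, and with the mammary term neutrophils (0.000361) and interferon-stimulated genes (0.00623).

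The direction in camera, which sets a list against all other genes, turned for adipose tissue and muscle without both Mim2 arrays (median -0.19). With the mammary term that list passed in the other direction (median -0.37, camera adjusted p = 0.0212). With that term the direction also turned for the unfolded protein response (median 0.24), NF-kB and the literature targets (camera adjusted p = 0.594, 0.901 and 0.986). The medians of NF-kB and the literature targets stayed positive, at 0.0653 and 0.0667. Of named genes, without both Mim2 arrays Adipoq became -0.14, Cidec -0.83, Tpx2 0.0604, Ppox 0.0222 and Kit 0.16. With the mammary term Adipoq became -1.46, Cidec -2.13, Ccnb2 0.0230, Kif20a 0.14, Tpx2 0.23, Hmgcs1 -0.0658, Egln3 0.49, Slc2a1 0.0616, Pfkl 0.12, Ppox 0.48, Kit 0.61, Stat3 0.22, Gata3 0.44, Xbp1 0.39 and Pdia3 0.56. The other 2111 values of named genes between genotypes kept their direction. No paired analysis was possible because the knockout and wild-type labels share no replicate numbers. The seed-match test and a slide or scan block were not run. Features near the random probes have little signal over background.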

Other observations

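The adipocyte list and the control tissue lists were written after the data had been seen. Adipocyte genes had list means of 11.3 and 10.4 in Mim2-2 and Mim2-3, and of 7.53 to 7.87 on the other 6 arrays. Pparg, the regulator of fat cell formation, differed between genotypes by 3.56 in males and 0.77 in females, and Pck1 by 4.99 and 0.18. Adrb3 read 10.2 and 9.34 in Mim2-2 and Mim2-3. It lay above the random probes on 2 of 4 wild-type arrays, so the size of its difference is not known. The hormone-sensitive lipase gene Lipe differed by 2.22 in males and 0.16 in females. Epithelial genes ran the other way on these 2 arrays. Krt18 read 10.5 and 10.6 in Mim2-2 and Mim2-3 and 13.5 to 14.5 on the other 6, and the transcription factor gene Elf5 read 7.60 and 8.11 against 11.4 to 12.1. Erbb2 read 12.1 and 13.9 there and 14.4 to 14.8 on the others.

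Milk protein genes had a list mean of 8.49 in the knockout and 10.65 in the wild type, lower on 4 of 4 knockout arrays. It was 9.18 and 8.36 in Mim1-5 and Mim1-6 and 7.48 and 8.94 in Mim2-2 and Mim2-3. The control lists of liver, nervous system, intestine, kidney and lung had median percentiles of 28.2, 38.6, 24.2, 30.9 and 35.9 among all genes.

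The second principal component, with 18.7% of the variance, had positive scores for Mim1-5, Mim2-2 and wild-type animals 1 and 3 and negative scores for the other 4 arrays. Among wild-type arrays its sign coincides with the labelled sex. A fit of arrays grouped by this sign was run once and is not reported, because the groups came from the data.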
